A study of Homo sapiens with 8 samples.

How the data were processed

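SiHa, an established line from a squamous cell carcinoma of the cervix, was seeded in wells of a transwell plate, in which cells can crawl through a porous membrane. After 10 h the cells that had crossed the membrane and those that had not were scraped off separately. From each fraction an input library, which holds sonicated chromatin without antibody, and a chromatin immunoprecipitation (ChIP) library made with an antibody to trimethylated lysine 9 of histone H3 (H3K9me3) were sequenced. This was done in 2 paired replicate sets, which gives 8 libraries in 4 groups, with n = 2 per group. Per the labels' protocols, set 1 was made with an Illumina kit and gel extraction and showed many duplicate reads, which were removed, while set 2 was a second biological replicate made with beads and another kit. The kit therefore differs between the sets but not between the fractions. The title of 1 set 1 library (H3K9me3 of migrated cells) and its description give different replicate numbers, and the title was followed.

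The deposited values were on a log2 scale per the file headers, for 38157 promoter windows in hg19. Of these, 36796 spanned 2100 bases, from 2000 bases upstream to 100 bases downstream of a start position, and 1361 were wider, as several windows of SNHG14 were. The submitters' processing notes name FastQC 0.11.5, Bowtie2 2.2.9 and SAMtools 1.3; the program that counted reads in windows is not given in the sources used here. The deposited log2 values were found to be the log2 of a whole read count plus 1 constant per library, with windows without reads entered as log2 of 0.9. After the constant was removed, 100% of values were whole within a tolerance of 0.01, and these recovered reads were used. How the authors chose the constants is not given in the sources used here. Each window carries the name of an Ensembl gene that overlaps it, so a window can start an antisense or alternative transcript of the named gene. Windows on the strand opposite to the gene include those listed for VIM, ZEB1, EHMT2, NOTCH1, MEST, MUC5B, MMP26 and DLG2, and the strand was not checked for every window, so a value given under a gene's name need not be that of its own promoter.

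The tests had been planned as a quasi-likelihood test of read counts. Because the deposited unit was log2, limma 3.58.1 in R 4.3.3 was used in its place, on log2 of the recovered reads plus 0.5 per library size, with precision weights from the mean-variance trend (voom). Library sizes were scaled with trimmed means of M values (TMM, with 30% of ratios and 5% of levels trimmed from each side). H3K9me3 over input is therefore relative to the centre set by TMM and not absolute. This centre is called the typical promoter below, although the median tested window lay at log2 -0.344 on this scale. Windows were kept where at least 2 libraries passed the level that equals 10 reads in a library of median size and the total was at least 15 reads, which left 36440 windows. The model held the replicate set, ChIP against input, their product, the fraction, and the product of fraction and ChIP, with 2 residual degrees of freedom and 33.2 prior degrees of freedom. The last term is the input-corrected change between the fractions. The set was kept as a block because the series describes paired sets; deviations of same-numbered libraries from their group means correlated at r = 0.147 for H3K9me3 and 0.469 for input across windows, which are not independent replicates. Calls were made at a Benjamini-Hochberg adjusted p of 0.05.

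The 29 gene lists tested were fixed before the data were examined, and those reported here are C2H2 zinc finger genes, olfactory receptors, clustered protocadherins, cancer-testis genes, keratins, keratin-associated proteins, cornified envelope genes, defensins, chemokines, type I interferons, taste and vomeronasal receptors, matrix metalloproteinases, collagens, integrins, ribosomal proteins, oxidative phosphorylation, replication-dependent histones, HOX genes, cytochrome P450 genes, epithelial adhesion genes, mesenchymal genes, the H3K9 methylation machinery, the Notch pathway, the TGF-beta pathway, cell cycle genes, imprinted genes, haematopoietic lineage genes and neuronal genes. All 29 were tested with limma's camera at a preset correlation of 0.01 over 24792 genes, each taken by its window with the most reads, and with fry, which asks whether a list departs from 0 rather than from other genes. The integrin list was matched by symbol and also caught ITGB3BP and ITGB1BP1, which are not integrins. The zinc finger list was matched by symbol too (ZNF, ZFP, ZSCAN and ZKSCAN), so that it holds some genes of other zinc finger types, such as ZFP36, and lacks C2H2 genes with other names, such as HKR1, ZIK1, ZIM2 and ZIM3.

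The rule for named genes was also fixed before the data were examined. For a change between the fractions it took passing rows with the same sign in both sets and a mean of at least 20 reads, up to 12 per direction, or else rows of smallest unadjusted p up to 6 per direction, given as not passing. For enrichment it took the 10 largest passing rows that lay above input in all 4 pairs with the same minimum of reads. Up to 4 members per list by unadjusted p were added, together with SUV39H1, SUV39H2, SETDB1, EHMT2, CDH1, CDH2, VIM, SNAI2, ZEB1, NOTCH1, MMP1, GAPDH and ACTB. Clone names, small RNAs and pseudogenes were passed over in the first 2 parts of the rule, and of overlapping windows the one with the most reads was named. GAPDH is not analysed here. Pooled read shares, a quasi-Poisson model of the recovered reads whose dispersions were squeezed with limma and held at 1 or above, a negative binomial model with 1 dispersion (0.0242) and F tests on deviances, and further scalings were added after the data had been seen.

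The fit was tested on simulated reads with the real library sizes and a dispersion of 0.02. Window means came from the real libraries of each set, pooled over the fractions. For ChIP over input they came from the input libraries alone. Changed windows were drawn only from those above a minimum of H3K9me3 reads in set 2, so the rates below do not cover windows with fewer reads. Of 100 windows changed 2-fold in the input-corrected change it recovered 0, and of 100 changed 4-fold it recovered 3. For ChIP over input it recovered 6 of 100 windows changed 2-fold and 51 of 98 changed 4-fold. No unchanged window was called in these simulations. The quasi-Poisson model recovered 0 of 100 and 0 of 100 changes, and 14 of 100 and 50 of 98 enrichments, in the same simulations; the negative binomial model recovered 0 of 100 and 0 of 100 changes, and 7 of 100 and 56 of 98 enrichments. Alternatives covered the scaling, the filter, the block, the weights, the model, overlapping windows, the input libraries, the gene list test and each library left out. Intervals of read shares are Wilson intervals at 95% and cover counting error only, since reads without molecular identifiers are not independent molecules.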

Results

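H3K9me3, a histone mark of silenced chromatin that SUV39H1 and related enzymes write, was measured at promoters of SiHa cells that had or had not crossed a transwell membrane within 10 h. Each of the 4 groups (input and H3K9me3 of non-migrated and of migrated cells) held 2 libraries, 1 per replicate set. The promoter windows of set 1 held 388191 reads in the non-migrated input, 164766 in the non-migrated H3K9me3 library, 684949 in the migrated input and 88028 in the migrated H3K9me3 library. In set 2 these numbers were 1729061, 1137376, 1679874 and 984835. The median window of the migrated H3K9me3 library held 1 read in set 1 and 17 in set 2, and 30.5% and 4.02% of its windows held none. Depth outside promoter windows is unknown. Values per gene below are log2 of H3K9me3 over input, averaged over both fractions unless stated, with limma's SE, n = 2 sets and hg19 positions. They are relative to the TMM centre, called the typical promoter. The median tested window lay at -0.344 on this scale, so a value slightly below 0 is not low among promoters.

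The first question was where the mark lay. The 10 named windows with the highest H3K9me3 included those of several zinc finger genes. ZNF208, a zinc finger gene on chromosome 19 (window 22193645 to 22195745), carried 8.42-fold more H3K9me3 than input (log2 3.07 ± 0.43, adjusted p = 2.35e-06 by limma), with 96 H3K9me3 against 27 input reads in non-migrated and 117 against 40 in migrated cells of set 2. Its non-migrated input of set 1 held 1 read, and set 2 alone gave log2 2.29 in non-migrated and 2.30 in migrated cells. CNTN4, a neuronal adhesion molecule (chromosome 3, 2138497 to 2140597), passed as well (adjusted p = 3.07e-05); its non-migrated input of set 1 held 0 reads, and set 2 gave log2 1.82 and 1.98. PDE10A, a phosphodiesterase (chromosome 6, 166075488 to 166077588), carried 6.88-fold more (log2 2.78 ± 0.46, adjusted p = 1.46e-05; 2.09 and 3.05 in set 2). The rest of the 10 highest named windows were SLC35G5 (log2 1.58 and 2.37 in non-migrated and migrated cells of set 2), ZFP28 (2.40 and 2.89), a minus-strand window within MUC5B (2.36 and 2.24), USP29 (2.28 and 2.43), LPHN2 (1.39 and 2.63), C19orf18 (2.22 and 2.49) and ZNF682 (2.19 and 2.75). Their order rests in part on inputs of few reads in set 1. In all, 4334 of 36440 windows (11.9%) were enriched and 11418 (31.3%) lay below the typical promoter in the limma test. The quasi-Poisson model called 4860 enriched and 6073 lower windows, and the negative binomial model 4711 and 11771, so the lower count depended on the model. These counts hold relative to the typical promoter, since the deposited constants moved the median window from log2 -0.34 to -1.30 and scaling to ribosomal protein and oxidative phosphorylation promoters moved it to 0.52.

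Enriched promoters lay close together in some regions. How many of the enriched windows lie in such regions was not measured. On chromosome 19, 131 of 224 genes with symbols of the C2H2 zinc finger list (58.5%) were enriched, with a median log2 of 1.22, against 49 of 249 such genes elsewhere (19.7%), where 60 lay below the typical promoter and the median was -0.135, and 159 of 1082 other genes on chromosome 19 (14.7%), of which 401 (37.1%) lay below. The other genes include a few zinc finger genes with other symbols, such as ZIK1 and HKR1. All 12 windows tested between 22000001 and 23000000 on chromosome 19, where ZNF208, ZNF98 and ZNF99 lie, were enriched, as were all 11 between 63000001 and 64000000 on chromosome 7, where ZNF727 and ZNF679 lie. On chromosome 15, 30 of 31 windows between 25000001 and 26000000 were enriched. They include 22 of 22 windows of SNHG14, a long noncoding RNA of the imprinted Prader-Willi region (25275020 to 25523590), with a median of 5.11-fold (log2 2.35); SNHG14 and these regions were singled out after their values were seen. Over whole chromosomes the enriched share was 25.2% on X and 20.8% on 19, and 4.67% on 17, and the share below the typical promoter was 6.15%, 35.5% and 44.5%.

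**Figure D1:**
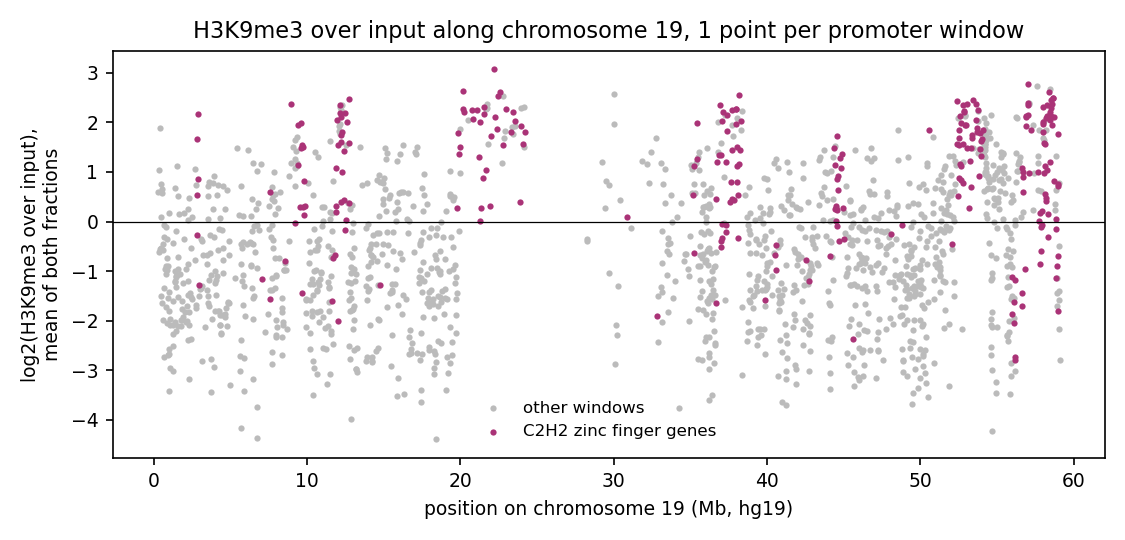
H3K9me3 over input (y axis, log2, mean of both fractions and sets from the limma fit) along chromosome 19 (x axis, Mb, hg19), with 1 point per promoter window. C2H2 zinc finger genes are coloured, and their median on this chromosome was 1.22; the median of zinc finger genes on all chromosomes, 0.48, turned to -0.52 under the deposited constants.

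Of the 29 gene lists, 7 ranked above other genes in camera at the preset correlation and 0 at an estimated one. Among C2H2 zinc finger genes, many of which encode DNA-binding repressors, 180 of 473 were enriched and 77 lay below the typical promoter. Their median log2 of 0.48 rested on the genes of chromosome 19. Over the list on all chromosomes, and not as examples of chromosome 19, ZNF623 (5.02-fold, adjusted p = 7.94e-08 by limma) and ZNF707 (4.97-fold) stood high, while ZNF425 lay at 0.0606 of input. Of cancer-testis genes, normally used in the germline, 25 of 40 were enriched and 0 lower (median 1.21), among them PAGE1 (3.90-fold) and MAGEB10 (3.27-fold). Of clustered protocadherins, adhesion molecules of neurons, 9 of 16 were enriched and 0 lower (median 1.05), with PCDHGA1 at 4.12-fold. Imprinted genes had 13 of 27 enriched and 4 lower (median 0.68), with an opposite-strand window of MEST at 4.37-fold and PHLDA2 at 0.129 of input. Neuronal genes had 13 of 38 enriched and 2 lower (median 0.63), with CNTNAP2 at 3.91-fold and an opposite-strand window of DLG2 at 3.68-fold. Olfactory receptors had 44 of 274 enriched and 5 lower (median 0.47), with OR2L13 at 5.57-fold, and cornified envelope genes 5 of 29 enriched and 0 lower (median 0.37). Adjusted over the list alone, the enriched members numbered 192, 28, 12, 13, 13, 25 and 0 in the order given. The adjusted p of these 7 lists in camera ran from 6.12e-10 (cancer-testis genes) to 0.0439 (cornified envelope genes). Fry found 15 of the 29 lists to depart from 0 in 1 direction and 28 in either. None of the 7 held with an estimated correlation, where the smallest adjusted p in camera was 0.452. That version rests on 2 residual degrees of freedom and has little power here. The estimated correlations of zinc finger genes (0.00667) and imprinted genes (0.000642) lay below the preset 0.01, yet these lists were lost too. Under the deposited constants, which lower all values, the medians turned negative except those of cancer-testis genes (0.32) and protocadherins (0.09).

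Promoters of 6 lists, from cell cycle genes to the Notch pathway, ranked below other genes in camera at the preset correlation. Of cell cycle genes, 21 of 33 were lower and 1 was enriched (median log2 -1.38), among them CCNE2, a cyclin (0.0868 of input), and PCNA, the replication clamp (0.118). Of oxidative phosphorylation genes 36 of 66 were lower and 1 enriched (median -1.21), with ATP5E at 0.0739. Of replication-dependent histone genes 21 of 40 were lower and 1 enriched (median -1.26), and of ribosomal protein genes 31 of 57 were lower and 2 enriched (median -1.09), with RPS21 at 0.0829. Of TGF-beta pathway genes 15 of 29 were lower and 0 enriched (median -1.18), and SMAD7, an inhibitor of the pathway, held 0 H3K9me3 reads in all 4 libraries against 34 and 24 input reads in set 2. Of Notch pathway genes 16 of 37 were lower and 1 enriched (median -1.08), with HES1, a Notch target, at 0.0901. Adjusted over the list alone, the lower members numbered 21, 37, 21, 33, 15 and 17 in the order given. Their adjusted p in camera lay between 0.000678 and 0.0235. None held with an estimated correlation (adjusted p = 0.452 in camera), a version that rests on 2 residual degrees of freedom. Their medians stayed negative under each scaling tried.

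**Figure D2:**
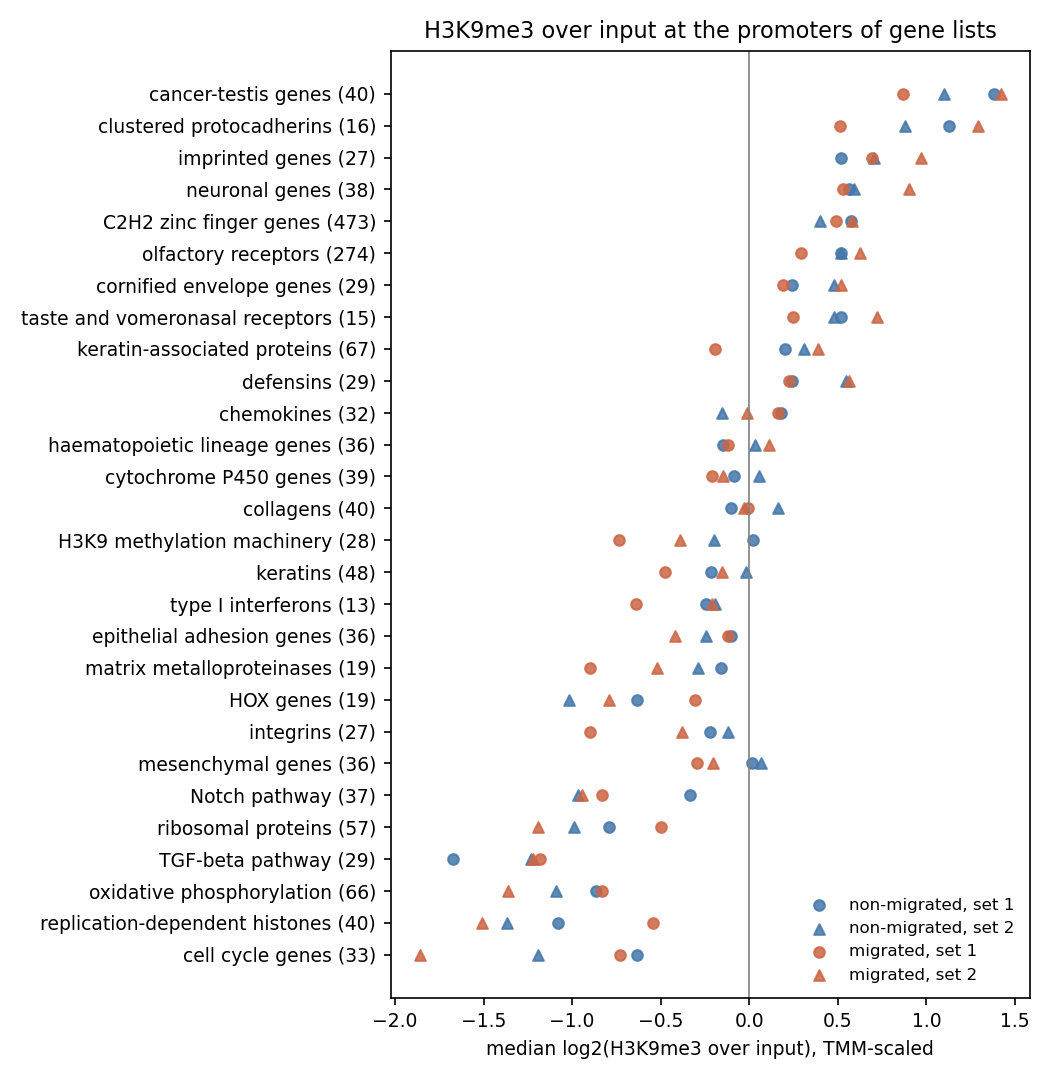
Median log2 of H3K9me3 over input (x axis, TMM-scaled) at the promoters of the gene lists reported (y axis, genes measured in brackets), with 1 point per pair of an H3K9me3 and an input library; colour gives the fraction and shape the replicate set. Cancer-testis genes lay between 0.87 and 1.42 in the 4 pairs and cell cycle genes between -1.86 and -0.63; under the deposited constants the medians of zinc finger, olfactory receptor, imprinted, neuronal and cornified envelope genes turned negative.

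The other lists reported here did not stand apart from other genes in camera (adjusted p of 0.0606 or more). Of integrins 10 of 27 lay below the typical promoter and 0 were enriched, with ITGAV, the vitronectin receptor subunit, at 0.139 of input; 2 of the 4 members of smallest p, ITGB3BP and ITGB1BP1, are not integrins. Mesenchymal genes split into 10 of 36 enriched, among them GSC (4.64-fold), and 13 lower, among them TNC (0.103) and SNAI1 (0.190). The H3K9 methylation machinery had 9 of 28 lower, among them KDM4B (0.102) and TRIM28 (0.222), and 2 enriched. HOX genes had 6 of 19 lower and 0 enriched, with HOXC10 at 0.274. Keratins had 8 of 48 lower, with KRT7 at 0.0851, and 3 enriched; epithelial adhesion genes had 4 of 36 lower, with PKP1 at 0.113, and 2 enriched. Matrix metalloproteinases had 2 of 19 enriched (MMP16 at 3.37-fold and a minus-strand window within MMP26 at 2.77-fold) and 4 lower. Collagens had 5 of 40 enriched, with COL22A1 at 3.02-fold, and 6 lower, and cytochrome P450 genes 5 of 39 enriched and 9 lower. Haematopoietic lineage genes had 5 of 36 enriched, with CD7 at 4.28-fold, and 6 lower. Taste and vomeronasal receptors had 4 of 15 enriched and 1 lower, keratin-associated proteins 4 of 67 and 2, defensins 3 of 29 and 0, chemokines 1 of 32 and 3, and type I interferons 0 of 13 and 1. Chemokines, collagens, cytochrome P450 and haematopoietic genes had negative medians and means while camera ranked them slightly high. Camera compares with other genes, and the median of all tested windows was itself -0.344. Adjusted over the list alone, the enriched and lower members were 0 and 10 for integrins, 11 and 13 for mesenchymal genes, and 2 and 9 for the methylation machinery.

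Among the genes named in advance, CDH2, the mesenchymal N-cadherin (chromosome 18, 25757310 to 25759410), was enriched 3.79-fold (log2 1.92 ± 0.40, adjusted p = 0.000211 by limma). A window on the strand opposite to ZEB1, a repressor of epithelial genes, was enriched 2.28-fold (log2 1.19 ± 0.48, adjusted p = 0.0429 by limma). The windows given below for EHMT2, VIM and NOTCH1 also lie on the strand opposite to the gene. Their values, like that for ZEB1, need not be those of the genes' own promoters. SNAI2 lay at 0.273 of input (log2 -1.87 ± 0.49, adjusted p = 0.00246), SUV39H2 at 0.178 (log2 -2.49 ± 0.49, adjusted p = 0.00012) and ACTB at 0.223 (log2 -2.16 ± 0.52, adjusted p = 0.000993). SUV39H1 itself did not differ detectably from the typical promoter (log2 -0.18 ± 0.41, adjusted p = 0.751), and neither did SETDB1 (-0.75 ± 0.45), EHMT2 (0.38 ± 0.52), CDH1, the epithelial E-cadherin (0.27 ± 0.28), VIM (0.90 ± 0.40, adjusted p = 0.0696), NOTCH1 (-0.52 ± 0.47) or MMP1 (-0.89 ± 0.50). The sign for SUV39H1, SETDB1, EHMT2, CDH1, VIM and NOTCH1 depended on the scaling or the model, and the calls for CDH2 and ZEB1 were lost under the deposited constants (log2 0.97 and 0.25). The call for ZEB1 was also lost with median-of-ratios factors (ChIP over input at ZEB1 1.09), without the input of migrated cells of set 1 (0.87), without the input of non-migrated cells of set 2 (0.87) and without the H3K9me3 library of non-migrated cells of set 2 (1.07).

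Most promoters called in non-migrated cells were also called in migrated cells. In non-migrated cells 1399 windows were enriched and 6039 lower, and in migrated cells 4866 were enriched and 10858 lower (limma). Of the 1399, 1331 (95.1%) were also enriched in migrated cells, and of the 6039, 5421 (89.8%) were also lower there. In reverse, 27.4% of the enriched and 49.9% of the lower windows of migrated cells were called in non-migrated cells. Calls in both fractions came from 1 fit with a shared spread per window, so the overlap is not agreement of separate fits. Across windows, which are not independent replicates, H3K9me3 over input in the 2 fractions correlated at r = 0.877 in set 2 and 0.469 in the shallower set 1. The larger number in migrated cells is not a test of a difference, and its size depended on the model. Limma's median SE was 0.618 in non-migrated and 0.497 in migrated cells, so the counts were not made at equal precision. The quasi-Poisson model called 1588 and 3329 enriched windows, and only 594 and 1253 lower ones. The negative binomial model called 2193 and 3359 enriched windows, and 7207 and 8664 lower ones. Without precision weights the counts of enriched windows in the fractions lay closer together, as given below. The number of promoters enriched for H3K9me3 over input in non-migrated cells became 184 without the migrated input and 3960 without the migrated H3K9me3 library of set 1, and 134, 3034, 437 and 2931 without the non-migrated input, the non-migrated H3K9me3, the migrated input and the migrated H3K9me3 library of set 2. The number of promoters enriched for H3K9me3 over input in migrated cells became 8109, 7845 and 861 without the non-migrated input, the non-migrated H3K9me3 and the migrated input library of set 1, and 2836, 1114 and 1874 without the non-migrated input, the migrated input and the migrated H3K9me3 library of set 2.

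The series title ties migratory cells to low SUV39H1, so the main question was whether H3K9me3 differed between the fractions. Relative to other promoters, enriched promoters took a larger share of H3K9me3 reads in migrated cells of both sets. The 4334 enriched windows took 29.8% of H3K9me3 reads in non-migrated and 34.4% in migrated cells of set 1 (95% Wilson intervals 29.6 to 30 and 34.1 to 34.7), and 30.3% and 35.7% in set 2 (30.3 to 30.4 and 35.6 to 35.8). Their share of input reads was 11.1% in both fractions of set 1, and 10.9% and 11.1% in set 2. The input-corrected ratio of reads in enriched to other windows was thus 1.23-fold higher in migrated cells in set 1 (log2 0.299 ± 0.02, SE over resampled chromosomes) and 1.25-fold higher in set 2 (0.319 ± 0.014). In the highest of 10 equal groups of promoters by H3K9me3 over input the share of reads differed by log2 0.19 in set 1 and 0.23 in set 2, and in the lowest by -0.12 and -0.57. The median change per window in that lowest group was 0.62 in set 1 and -0.39 in set 2. The value in set 1 does not show a direction. A window without H3K9me3 reads in either fraction takes its value from the 0.5 added to each count, the library sizes and the input. The smaller size of the migrated H3K9me3 library of set 1 raises that value, and 30.5% of its windows held no reads. How many of these lay in the lowest group was not counted. Pooled over their members, C2H2 zinc finger genes took a larger share in migrated cells in both sets (log2 0.14 and 0.15), as did imprinted genes (0.15 and 0.23), neuronal genes (0.19 and 0.27) and protocadherins (0.11 and 0.24, with 71 reads in the migrated H3K9me3 library of set 1). The median change per member in set 1 was instead -0.32 for protocadherins, 0.01 for neuronal and zinc finger genes, and 0.09 for imprinted genes. Of the other 3 enriched lists, olfactory receptors took a smaller share in both sets (-0.14 and -0.03), cornified envelope genes hardly differed (-0.00708 and -0.00487), and cancer-testis genes differed in sign (-0.23 and 0.33). The larger shares of lists were not separated from the rise of the highest group of promoters as a whole, so they need not be particular to the lists. Reads were pooled only after the values per window had been seen, and the pooled values were not tested across the 2 sets.

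**Figure D3:**
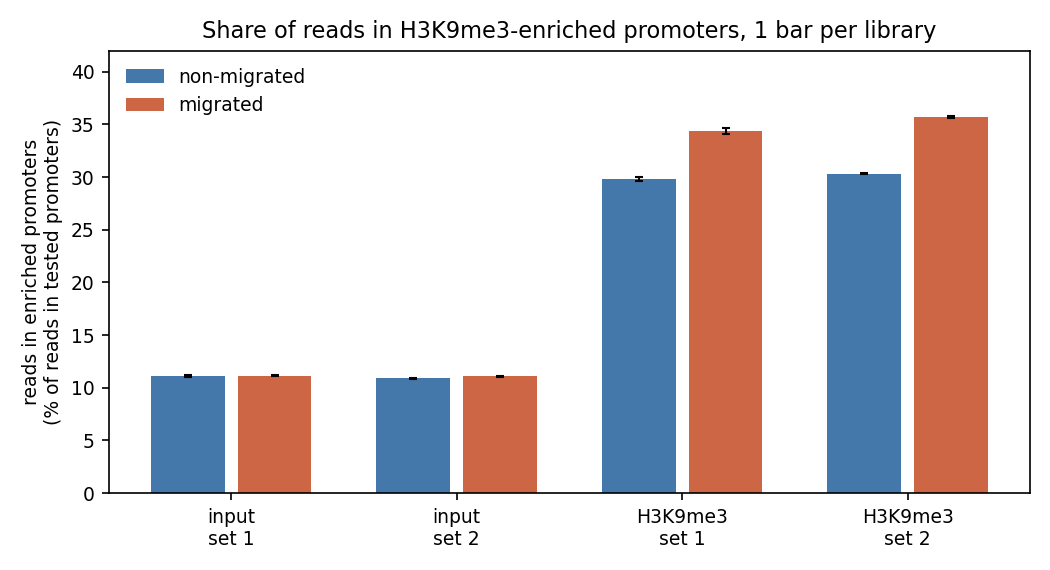
Share of reads that fell in the 4334 H3K9me3-enriched promoters (y axis, % of reads in tested promoters, starting at 0), with 1 bar per library and 95% Wilson intervals for counting error as error bars. H3K9me3 libraries of migrated cells reached 34.4% and 35.7%, those of non-migrated cells 29.8% and 30.3%, and inputs 10.9% to 11.1%.

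**Figure D4:**
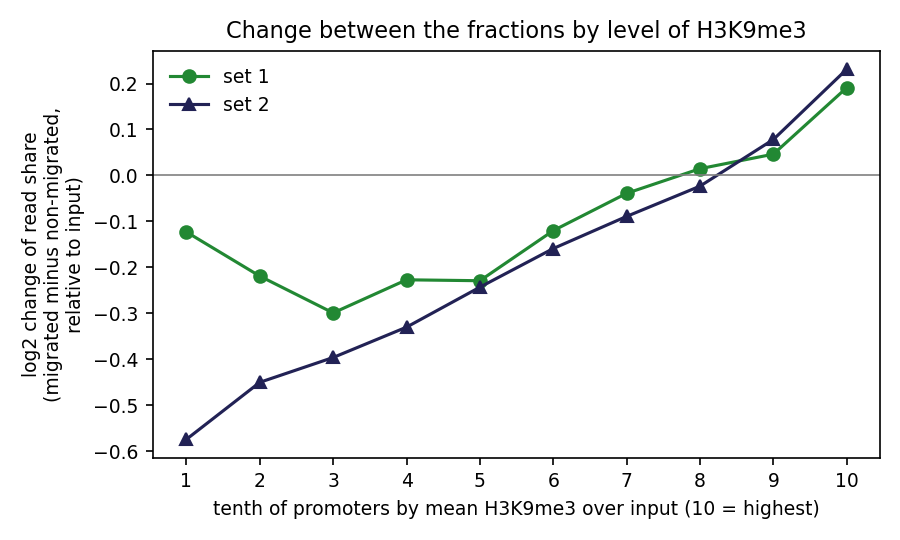
Change of the share of reads, migrated minus non-migrated and relative to input (y axis, log2), in 10 equal groups of promoters ordered by mean H3K9me3 over input (x axis), with 1 line per replicate set. In the highest group the change was 0.19 in set 1 and 0.23 in set 2; in the lowest it was -0.12 and -0.57.

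The measure fixed in advance, the median of the input-corrected change per window, was log2 0.28 at enriched and -0.07 at other windows (difference 0.35 ± 0.01, SE over resampled chromosomes). In camera the enriched windows ranked above the others with p = 3.34e-12 at the preset and p = 0.0512 at an estimated correlation. The latter rests on 2 residual degrees of freedom. Taken per set, the medians of enriched and other windows were 0.07 and -0.07 in set 1, and 0.30 and -0.09 in set 2, where 74.1% of enriched windows lay above 0. In the fits with 1 library left out, enriched windows were called anew, so they are not the same windows as above. Without the non-migrated H3K9me3 library of set 2 the difference turned to -0.34 and the median at enriched windows to -0.24. Whether the windows or their values moved was not separated. The median input-corrected change at H3K9me3-enriched promoters and the difference in median change between enriched and other promoters were 0.13 and 0.189 without the non-migrated input of set 2, and 0.564 and 0.661 without the migrated input of set 2. Under the deposited constants the median at enriched windows was -0.61, above that of other windows by 0.34. Enriched windows were called anew there too, and far fewer were called in each fraction, so this value covers another set of windows.

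No single promoter passed the test of a change between the fractions. Limma called 0 of 36440 windows (1286 at an unadjusted p under 0.05, smallest adjusted p 0.999), and the quasi-Poisson and negative binomial models called 0 as well (1496 and 1221 at an unadjusted p under 0.05). A fit of the H3K9me3 libraries alone, without input, had fewer residual degrees of freedom than the main fit. Its SEs and calls therefore lean more on the prior. In it 55 windows were higher in migrated cells and 0 lower. They include IRX4, a homeobox gene on chromosome 5 (log2 0.73 ± 0.11, adjusted p = 0.00892 by limma). An opposite-strand window of DLG2, a synaptic scaffold (0.62 ± 0.10, adjusted p = 0.00979 by limma), was among them. So were CHAT, which makes acetylcholine (1.70 ± 0.30, adjusted p = 0.0164 by limma), and 4 windows of SNHG14 (log2 0.348 to 0.554), some of them wider than 2100 bases. Apart from DLG2 these were chosen after their values were seen. Most H3K9me3 reads of these windows came from set 2, where IRX4 held 323 and 433 reads in non-migrated and migrated cells, against 22 and 25 in set 1. In the H3K9me3 libraries without input, enriched windows as a class were higher in migrated cells relative to other windows. This shift was log2 0.304 in set 1 and 0.349 in set 2 for pooled reads. The calls were not separated from it, so they need not be changes of single promoters. In fits without 1 library, 42 promoters with an input-corrected H3K9me3 change in migrated cells were called without the non-migrated H3K9me3 library of set 2, 5 without the migrated one, and 1 without the non-migrated input of set 1. The simulations described above recovered 3 of 100 input-corrected changes of 4-fold, so changes of that size at single promoters were mostly not detectable at this depth.

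The promoters of smallest p with the same sign in both sets were listed although none passed the input-corrected test (adjusted p = 0.999 by limma). Higher in migrated cells were BARHL1, a neural homeobox gene (chromosome 9, 135455572 to 135457672; log2 1.42 ± 0.40), ZNF98 (1.47 ± 0.48), C5orf17 (1.16 ± 0.36) and LINC00273 (0.72 ± 0.20). With the H3K9me3 libraries alone, BARHL1 (adjusted p = 0.0141 by limma), C5orf17 (adjusted p = 0.00979) and LINC00273 (adjusted p = 0.00979) were among the 55 higher windows. LINC00273 turned to -0.22 under the deposited constants. PAPD7 and LRP8 held 0 H3K9me3 reads in non-migrated cells of both sets, and 8 and 5 in migrated cells of set 2. Lower in migrated cells were C3orf25 (-2.50 ± 0.74), WDR82 (-2.56 ± 0.80), ZNF512B (-2.53 ± 0.80) and DYNLRB1, a dynein light chain (-2.30 ± 0.72). ARL16 and DONSON held 19 and 8 H3K9me3 reads in non-migrated cells of set 2, and 0 in migrated cells of both sets. In non-migrated cells these 6 promoters lay between 0.278 (ZNF512B) and 0.725 (C3orf25) of input.

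Of the 29 gene lists, 2 differed between the fractions in camera. Cancer-testis genes (median change log2 0.37, adjusted p = 0.0474) and imprinted genes (0.24, adjusted p = 0.0474) ranked higher in migrated cells. With an estimated correlation, where camera rests on 2 residual degrees of freedom, adjusted p = 0.987 for cancer-testis genes and adjusted p = 0.95 for imprinted genes. Fry gave 0.99 as the smallest adjusted p of the 29 lists (0.952 for changes in either direction). The median of cancer-testis genes was -0.53 in set 1 and 0.51 in set 2. In no list did a single member pass, over all genes or adjusted over the list alone. Matrix metalloproteinases (median change -0.11), integrins (-0.31), epithelial adhesion genes (-0.08), mesenchymal genes (-0.11) and the H3K9 methylation machinery (-0.30) were not told apart from other genes in camera (adjusted p of 0.162 or more). Camera ranked mesenchymal genes slightly high although their median was negative. Without the replicate block 0 lists passed, as without any 1 of the 4 libraries of set 2.

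The input libraries served as the background of the comparison. Migrated and non-migrated input differed at 0 of 36440 windows (limma, 570 at an unadjusted p under 0.05, and 0 windows in the quasi-Poisson and negative binomial models with 1355 and 467 at an unadjusted p under 0.05).

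As deposited, with the authors' constants, most promoters read lower in the H3K9me3 libraries of migrated cells. In set 1 the median difference was log2 -0.92, with 87.3% of windows lower, while input differed by 0.84 in the other direction. In set 2 the median difference was -0.23, with 64.8% of windows lower, and input differed by -0.06. Promoter reads of migrated over non-migrated input stood at a ratio of 1.76 in set 1 and 0.972 in set 2, although the inputs' constants were nearly equal. For the H3K9me3 libraries this ratio was 0.534 in set 1 and 0.866 in set 2. Their constants were log2 0.748 (non-migrated) and 0.412 (migrated) in set 1, and 0.079 and 0.173 in set 2. At single promoters the change did not correlate between the sets (r = -0.00949, Spearman's coefficient 0.00134 across windows; r = 0.0411 among enriched windows), and 50.5% of windows, or 52.7% of the enriched ones, had the same sign in both. H3K9me3 over input did correlate between the sets (r = 0.658 in non-migrated and 0.602 in migrated cells).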

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

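Some of the scalings (median-of-ratios, deposited constants, summed reads), the fit without weights, set 2 alone, the quasi-Poisson and negative binomial models and the pooled reads were chosen after the data had been seen. The planned quasi-likelihood test was run on the recovered reads only outside the tables used here, where it also called 0 changed promoters and gave counts of enriched promoters closer to each other in the 2 fractions than limma did; the second planned count tool was not run, the correction for GC content was not run because no genome of this build was used here, and at least 30 reads in every library left 17 windows, too few to fit. The count of 0 promoters with an input-corrected H3K9me3 change in migrated cells held under every setting except the H3K9me3 libraries alone (55) and some with 1 library left out (0 to 42; 42 without the non-migrated H3K9me3 library of set 2, 5 without the migrated one, 1 without the non-migrated input of set 1). The count of 0 for promoters differing between migrated and non-migrated input held under each setting.

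The numbers of promoters enriched for H3K9me3 over input in non-migrated cells and of promoters enriched for H3K9me3 over input in migrated cells were 4687 and 10574 with TMM on ribosomal protein and oxidative phosphorylation promoters, 6458 and 11434 with the summed reads of these, 105 and 35 with the deposited constants, 2164 and 3160 without weights, and 134 to 3960 and 861 to 8109 with 1 library left out. The non-migrated count was 2193 with the negative binomial model, 2105 without a filter, 5558 with the replicate block but no set by ChIP term, and 2169 with 1 row per set of overlapping windows. Without the replicate block the counts were 2051 and 3603, and the count of changed promoters stayed at 0. A scaling sets the level of the typical promoter; for the other moves the cause was not tested.

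The median input-corrected change at H3K9me3-enriched promoters (0.28) and the difference in median change between enriched and other promoters (0.345) were 0.0708 and 0.142 in set 1 alone, 0.298 and 0.39 in set 2 alone, 0.361 and 0.405 when called in set 1 and measured in set 2, and -0.0301 and 0.0214 the other way round. The median was -0.609 with the deposited constants. With 1 library left out the median ranged from -0.244 to 0.564 and the difference from -0.344 to 0.661. Both reversed only without the non-migrated H3K9me3 library of set 2 (-0.244 and -0.344). Enriched windows were called anew with the deposited constants and in each fit with 1 library left out. A change in the choice of windows was therefore not separated from a change in their values, and the cause was not tested. The ratio of reads in enriched to other promoters (0.309) was 0.217 when called in set 2 and measured in set 1, 0.327 without input, and between 0.299 and 0.319 otherwise.

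Gene lists with an input-corrected H3K9me3 change (2) numbered 0 with column totals, without the replicate block and with an estimated correlation, 4 with all rows of each gene, and 0 to 3 with 1 library left out. Gene lists enriched for H3K9me3 over input (7) numbered 0 with an estimated correlation, where camera rests on 2 residual degrees of freedom. ChIP over input at SUV39H1 reversed to 0.66 and 0.68 with the 2 scalings to ribosomal protein and oxidative phosphorylation promoters, 0.067 without a filter, 0.18 without the replicate block, 0.30 without the set by ChIP term, and ranged from -0.55 to 0.20 with 1 library left out. ChIP over input at SETDB1 reversed to 0.0574 and 0.0861 and ChIP over input at NOTCH1 to 0.40 and 0.39 with these scalings (-0.94 to 0.07808 with 1 library left out), at EHMT2 to -0.14 without the set by ChIP term and -0.44 with the deposited constants, and with the deposited constants at CDH1 to -0.60, ChIP over input at VIM to -0.05519, ChIP over input at DEFB134 to -0.001055 and the change at LINC00273 to -0.22. Of 2329 values of ChIP over input at 137 named promoters under these settings, 2059 kept their direction and side of the threshold, 219 (at 61 of the 137) fell below it and 30 passed it; of 209 values of a change at 12 promoters, 205 did not move across it. With 1 library left out, the lone library of its group is assumed to vary like the others.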

Other observations

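The tests on the deposited scaling and on the share of reads in enriched promoters were chosen after the results had been seen; those on the correlation between the sets were fixed before.

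Enriched promoters also lay in further runs, which were picked after their values were seen. Between 146000001 and 147000000 on chromosome X, where the microRNAs MIR508 and MIR510 lie, 11 of 13 windows were enriched, and between 53000001 and 54000000 on chromosome 19, where ZNF816 and ZNF160 lie, 21 of 24. On chromosome 1, 9 of 10 windows between 238000001 and 239000000 were enriched, next to RYR2, a calcium channel of the heart. On chromosome 11, 9 of 12 windows between 133000001 and 134000000 were enriched, near OPCML and IGSF9B, adhesion molecules of neurons.

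Pooled over their members, several lists took a smaller share of H3K9me3 reads in migrated cells of both sets. They include keratins (log2 -0.23 in set 1 and -0.21 in set 2), cytochrome P450 genes (-0.22 and -0.22), keratin-associated proteins (-0.19 and -0.13), matrix metalloproteinases (-0.09 and -0.17), Notch pathway genes (-0.77 and -0.13), integrins (-0.47 and -0.18) and the H3K9 methylation machinery (-0.51 and -0.15). In set 1 the last 4 values rested on 41, 39, 43 and 51 reads of the migrated H3K9me3 library. None of these lists changed in camera (adjusted p = 0.0937 for cytochrome P450 genes and 0.281 for the Notch pathway). Cell cycle genes differed in sign between the sets (0.04 and -0.43). Mesenchymal genes took a larger share in both sets (0.49 in set 1, with 104 reads of the migrated H3K9me3 library, and 0.06 in set 2). Their median change per member in the fit had the other sign (-0.11).

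Under the deposited scaling most promoters read lower in the H3K9me3 libraries of migrated cells. A loss of the mark at the promoters that carry it would lower their reads relative to other promoters, and the ratio of pooled reads was instead higher by log2 0.299 (SE over chromosomes 0.02) in set 1 and 0.319 (0.014) in set 2. With 1 pair of libraries per set, a difference in pull-down between single libraries moves this ratio too, so a loss stays open. The deposited constants do not account for the lower values in set 2, since they raised the migrated H3K9me3 library (log2 0.173 against 0.079). In set 1 they were 0.412 and 0.748, a smaller gap than the median difference of -0.92. Promoter reads of migrated over non-migrated H3K9me3 libraries stood at 0.534 in set 1 and 0.866 in set 2. A loss in equal proportion at all promoters and a shift common to a library, such as its number of reads, cannot be told apart. Scaling to a common centre brings the median to -0.0428 in set 1 and -0.03 in set 2 either way. A biological difference between the fractions stays open.

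A larger share of H3K9me3 reads lay in enriched promoters in migrated cells of both sets. Choosing the promoters on the same libraries does not account for it as a whole. The 1017 promoters called in set 1 gave 0.302 (SE over chromosomes 0.021) in set 2. The 8285 promoters called in set 2 gave 0.217 (SE over chromosomes 0.015) in set 1. These SEs leave out the spread between libraries. On the measure fixed in advance, the promoters called in set 2 had a median change of -0.0301 in set 1. The difference in median change between enriched and other promoters was 0.0214 there. More background reads in the non-migrated H3K9me3 libraries, for example from a less efficient pull-down, cannot be told apart from a higher level of the mark in migrated cells. Both would lower the share of the lowest of 10 equal groups of promoters, which differed by -0.123 in set 1 and -0.574 in set 2, and shares sum to a fixed total. In set 1 the share fell further in the next groups (to -0.299). The median change per window of the lowest group was 0.619 there, which does not show a direction. Windows without H3K9me3 reads in either fraction take their value from the 0.5 added to each count, the library sizes and the input. A hypothesis that stays open is that migrated cells may hold a sharper contrast between marked and unmarked promoters, which reference chromatin of known amount could decide.

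The change at single promoters had a correlation near 0 between the sets (r = -0.00949, and 0.0411 among enriched promoters). When set 2 was thinned to the depth of set 1 in 20 draws, its change correlated with that of its own remaining reads at a mean r of 0.0521 (SD 0.00374), or 0.0754 among enriched promoters. The 2 thinned parts share the same libraries, so counting error at this depth could leave little correlation even between like samples; the gap between 0.0521 and -0.00949 fell between the bounds set in advance and leaves this explanation open. The library kit and the duplication of set 1 are confounded with the sets, and no value here separates them from a true difference between the biological replicates.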
